A study of Mus musculus with 15 samples.

How the data were processed

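Gene expression was measured in 15 libraries of Rex1 reporter mouse embryonic stem cells in 5 groups of 3. Per the labels, cells were grown with LIF for about 18 h to about 24% confluence, then kept for 72 h in their condition, lysed in Trizol and prepared by Lexogen's QuantSeq 3' protocol, which yields about 1 tag per transcript near its 3' end, so that counts do not scale with gene length. Each of the 4 deposited tables set the 3 NS libraries beside the 3 libraries of another group, and the NS values were identical in all 4 tables. Base calling used CASAVA 1.8.2, alignment used STAR and counting used HTSeq on the mouse build mm9, and the authors' own tests used edgeR, per the submitters' processing notes. The versions of STAR, HTSeq and edgeR, the gene annotation, the strand setting and the filters are not given in the sources used here. The deposited counts were whole numbers per gene symbol, and they were the input of all tests here. The deposited signal columns were the means of each group's raw counts, not scaled for depth, and were not used further, nor were the SDs beside them. The authors' log2 columns held the log2 fold change against NS and the log2 CPM, the authors' fold column held the same change as a signed fold, and the deposited score was the likelihood ratio statistic. The deposited p-value and FDR columns covered all genes of a table, and the FDR was used only to count the authors' own calls. A column headed as error held no values and was not used here, and 0 columns were left without a sample.

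The tables listed 21516 gene symbols, of which 4119 had 0 counts in all libraries, 291 had no Ensembl identifier and 1974 shared an identifier with another symbol. Counts of near-identical genes (Rpl10l, Rpl39l, Rps6 and other ribosomal protein genes with pseudogenes, histone genes, Pou5f1, Xlr3a, and Gpx2 with Gpx2-ps1) depend on how multiply aligned reads were treated and are uncertain. Coordinates are left out because the reference annotation used here, GENCODE M21, is of another build than the authors' mm9. It served only for GC content and transcript length, which 9341 of the 9390 tested genes (99.5%) had. Between 12407 and 14657 genes were detected per library, and the 10 most abundant genes took 6.10 to 9.46% of the counts. Pairs of libraries of 1 group differed by far more than sampling noise, with chi-square per degree of freedom of 2.45 to 29.3, so none was treated as a duplicate. Intervals and floors cover counting error only, since no molecular identifiers were used.

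Tests used edgeR 4.0.16 (glmQLFit and glmQLFTest) with TMM factors, filterByExpr (minimum count 10, minimum total 15) and Benjamini-Hochberg adjustment at 0.05, in R 4.3.3. All 15 libraries entered 1 fit with a coefficient per group and no block, which tested 9390 genes, except the dose trend, a linear slope per 50 mM over the 9 sorbitol libraries, which tested 8928. CPM values were computed with TMM factors, and their errors are the SD over libraries. The SE of a log2 change is its absolute value over the square root of the test's F statistic. It thus holds no evidence beyond the test itself. The p-values measure the spread between replicates that the labels describe as biological triplicates. Of 26 gene lists, the 25 with at least 3 measured members were tested with limma 3.58.1's camera at a preset correlation of 0.01 (it compares a list's genes with all others), with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. The ratio of a gene with 1 to 3 counts in a group was given with an exact binomial 95% interval. Shared calls were set against independent lists and against 20 simulated sets of unchanged groups. In each set all 15 libraries, NS included, were drawn independently from the NS means, and the comparisons shared the drawn NS libraries.

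The text names genes by a rule fixed before the data were examined. It takes Zfp42, Nanog, Pou5f1, Sox2, Fgf5, Gata6, Gata4, Sox17, Dab2, Cdx2, T, Slc5a3 and Akr1b3 always. It adds the 5 highest and 5 lowest log2 changes past the threshold with at least 20 CPM in the higher group and no overlap between the libraries. It also adds up to 4 members of each list past the list test, or with at least 3 members past the threshold, with at least 20 CPM. List members named outside it beside a count (Hspa1b, Slc5a5, Gpi1, Ldha, Rhox6, Hoxc13, at 250 mM Meg3, and at 200 mM Gata2, Col4a2 and Plac1), and Sycp3 at 300 mM and Pramel7, were chosen after their values were seen. The values of 1 list member past the threshold are not reported here.

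Since the groups share replicate numbers, the deviations from the group means were correlated between libraries of 1 number, and the correlation exceeded 0.1 in 24 of 30 such pairs. All 3 pairs exceeded it in 4 of the 10 pairs of groups. These were NS with 200 mM (0.69, 0.12 and 0.63 for replicates 1, 2 and 3), ND with 200 mM (0.63, 0.48 and 0.54), 200 with 250 mM (0.34, 0.16 and 0.20) and 250 with 300 mM (0.45, 0.21 and 0.30). The pairing was taken from this check alone, as the labels do not say what a number shares. Depth and GC content also went with the number. Replicate 1 was the deepest library of every group. Replicate 3 had the lowest Spearman correlation of the genes' deviations with GC content in every group (-0.26, -0.245, -0.284, -0.019 and -0.122 in NS, ND, 200, 250 and 300 mM). Neither tells whether cultures were shared. Among the comparisons of 2 groups, sorbitol at 200 mM minus NS is the 1 between groups that passed this check. There the highest correlation between libraries of different numbers was 0.19, above the 0.12 of replicate 2, so the pairing is uncertain. It was -0.11, 0.08 and 0.07 in the remaining pairs of groups that passed. NS with ND (0.59, 0.07 and 0.46) missed the cutoff in replicate 2 alone. The dose trend and the sorbitol mean minus ND each hold some pairs of groups that passed this check and some that did not.

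The test was tried on simulated counts with known changes in about 9350 genes per comparison with NS. It recovered 78.0% of 4-fold changes for ND minus NS (9358 genes), 73.0%, 66.0% and 74.7% for 200, 250 and 300 mM minus NS, 77.0% for 300 minus 200 mM, 92.6% for the trend (8868 genes) and 91.7% for the sorbitol mean minus ND. Of 2-fold changes it recovered 15.2%, 10.0%, 7.10%, 18.2%, 14.0%, 25.5% and 34.3% in the same order. It called 7, 10, 2, 4, 6, 7 and 8 unchanged genes. These counts were drawn without any bias by GC content. When a trend with GC content was put into the 3 NS libraries, the test of 300 mM minus NS called 404 of 9123 unchanged genes, and 7 with the correction for GC content and length, and recovered 77.8% and 75.8% of 4-fold changes. In the real libraries, the Spearman correlation of the genes' deviations with GC content ran from -0.284 in Sorb200 3 to 0.21 in Sorb300 1. It was 0.148, 0.074 and -0.26 in NS 1, NS 2 and NS 3. The correlation with transcript length ran from -0.205 in ND 2 to 0.149 in ND 1. Alternatives planned before the data were examined were RLE factors, library totals, no filter, a minimum of 5 CPM, DESeq2 1.42.0, the replicate block, a fit of the compared groups alone, a test against a 1.5-fold change and leaving out each library. Added later were replicates 2 and 3 alone, the likelihood ratio test without a filter, and a correction for GC content and length (a spline of 5 degrees of freedom per library) with and without the block. Planned settings for normalized values or for tables without counts were not run because the tables held counts. Tables and plots were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.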

Results

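Mouse embryonic stem cells of a reporter line, in which the promoter of Rex1 (Zfp42, a marker of undifferentiated cells) drives a red fluorescent protein, were profiled by 3' tag RNA sequencing after 72 h in 5 conditions. The NS group (normal stemness, per the labels) kept leukaemia inhibitory factor (LIF), the cytokine that holds mouse stem cells undifferentiated through STAT3, and the ND group (normal differentiation) grew without it. The other groups kept LIF and received sorbitol, a sugar alcohol that raises the osmolarity of the medium, at 200, 250 or 300 mM. Each group held 3 libraries, described as biological triplicates, which made 15 in all. Total counts per library ran from 968556 to 2289528. Replicate 1 of each group was the deeper one, with 1872918 to 2289528 counts, against 968556 to 1229075 in replicates 2 and 3, and 3 counts amounted to between 1.31 and 3.10 CPM (the count scaled to a common library total). The files listed 21516 genes, of which 9390 had enough counts to be tested. Expression of the 77 ribosomal protein genes was uneven among the libraries: relative to the mean of all 15, their median stood at -0.50 in NS 1 and -0.44 in NS 2 on the log2 scale, against 0.15 in NS 3, 0.83 in ND 2 and between -0.12 and 0.13 in the remaining 11 libraries. Dppa5a, an RNA-binding protein gene of undifferentiated cells chosen after its values were seen, was also uneven within NS, at 11.5, 20.9 and 458 CPM in NS 1, NS 2 and NS 3.

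Withdrawal of LIF for 72 h lowered 3 genes past the threshold. Klf4, a transcription factor of the naive pluripotency network and a target of STAT3, fell from 258 ± 132 to 44.7 ± 15.8 CPM (SD, n = 3 per group), a log2 change of -2.50 ± 0.41 (SE). Its adjusted p was 0.0473 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Bcl3, a nuclear IκB family member induced by STAT3, fell by 2.69 ± 0.37 on the log2 scale (adjusted p = 0.015). Tdgf1, which encodes the Nodal co-receptor Cripto, fell by 1.32 ± 0.22 (adjusted p = 0.0473). Nanog (-0.26 ± 0.58), Zfp42 (-0.40 ± 0.61), Sox2 (-0.46 ± 0.30) and Pou5f1 (-0.49 ± 0.39), the last of which has near-identical pseudogenes that could share its reads, did not pass. The primitive streak gene T had 4 counts in ND and 5 in NS, and Fgf5, a marker of the formative epiblast, had 9 and 0. The endoderm genes Sox17 and Gata4 had 10 and 5, and 5 and 7, all too few to be tested.

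Among the gene lists fixed before the data were examined, the LIF and STAT3 targets moved down as a group after LIF withdrawal, and 10 of the 11 measured members had negative fold changes (camera with a preset correlation, adjusted p = 4.5e-08, and 0.00255 with an estimated correlation). Of these members 2 fell, Klf4 and Bcl3, and 3 did when adjusted over the list alone. The naive pluripotency list moved down (adjusted p = 1.06e-05, and adjusted p = 0.26 with an estimated correlation), with 1 of its 18 members past the threshold and 4 adjusted over the list alone. The general pluripotency list moved down as well (adjusted p = 0.00157, and adjusted p = 0.333 with an estimated correlation), with 1 of 12 members past and 1 adjusted over the list alone. No member passed in the lists that moved up. These were the trophoblast list of 15 genes (adjusted p = 0.000324, and adjusted p = 0.13 with an estimated correlation; 4 up and 1 down adjusted over the list alone), the formative list of 14 (0.0186, and adjusted p = 0.26 with an estimated correlation; 2 up adjusted over the list alone) and the glycolysis list of 21 (0.000979, and adjusted p = 0.333 with an estimated correlation). The p53 list of 20 genes (0.00865, and adjusted p = 0.426 with an estimated correlation) and the oxidative phosphorylation list of 45 (0.0259, and adjusted p = 0.596 with an estimated correlation) moved the same way. The ribosomal protein list gave an adjusted p of 4.57e-17, lost at adjusted p = 0.26 with an estimated correlation, with 0 of 77 members past in edgeR. That list moved with the libraries, since its median change was 0.51 between the libraries of replicate 1, 1.13 between those of replicate 2 and -0.04 between those of replicate 3.

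The 3 calls between ND and NS were lost in most fits that left out 1 library, in 5 of 6 for Klf4 and Tdgf1 and in 4 of 6 for Bcl3. Without NS 1, NS 2, ND 1 or ND 2 the test called 0 genes, without ND 3 it called 2, and without NS 3 it called 74, of which 46 were higher and 28 lower. DESeq2 called 33, and a fit of the ND and NS libraries alone called 0 in edgeR. Of the 9390 tested genes, 600 had an unadjusted p under 0.05 in edgeR. A share of 0.05 of unchanged genes passes that level on average, here and in the unadjusted counts given further on. With replicates 2 and 3 alone, a setting chosen after the data were seen, 0 genes passed, and replicate 1 has 1 library per group and allows no test. The adjusted p of Klf4 rose to between 0.112 and 0.371 without any 1 library except NS 3, that of Tdgf1 to between 0.109 and 0.371, and that of Bcl3 to between 0.0515 and 0.158 without NS 1, NS 2, ND 1 or ND 2. Among the lists, the LIF and STAT3, trophoblast and ribosomal calls stood without any 1 library. The naive call was lost without NS 3 (adjusted p = 0.102), the general call without NS 1 (0.093) or ND 2 (0.173), and the glycolysis call without ND 2 (0.204). The formative call was lost without NS 1 (0.0506), NS 3 (0.161), ND 1 (0.297) or ND 3 (0.155), and the p53 call without NS 1 (0.101) or ND 2 (0.456). The oxidative phosphorylation call was lost without NS 1 (0.163), NS 2 (0.0869) or ND 2 (0.949).

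**Figure D1:**
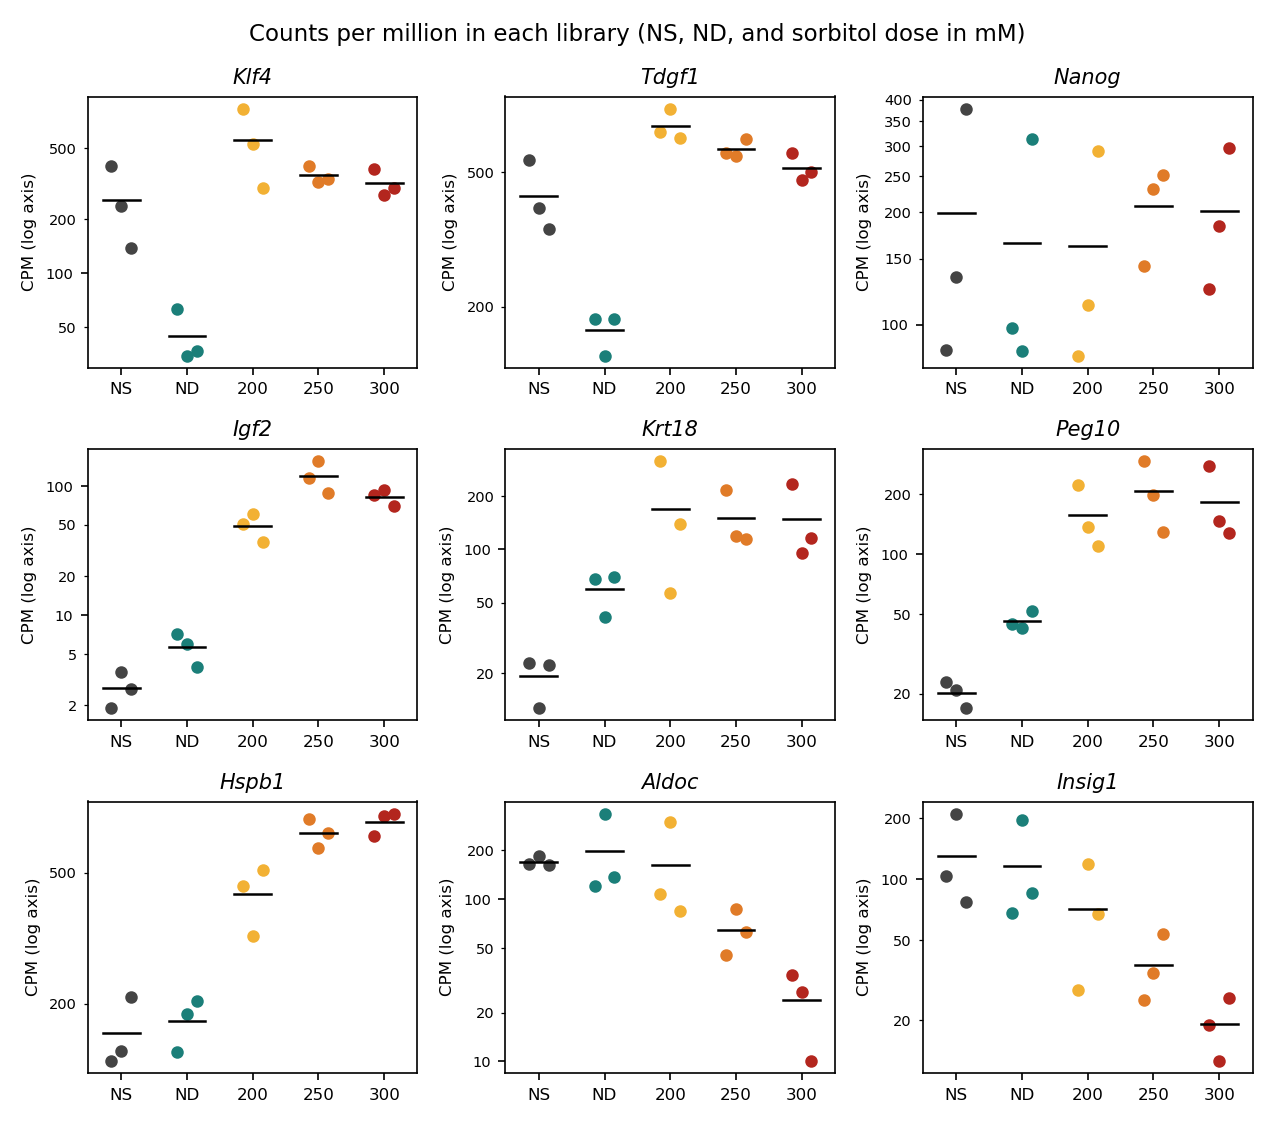
CPM (log axis) of Klf4, Tdgf1, Nanog, Igf2, Krt18, Peg10, Hspb1, Aldoc and Insig1 in each of the 15 libraries, grouped as NS, ND and sorbitol at 200, 250 and 300 mM, with 1 point per library and a black line at the mean of 3. Klf4 averaged 258 CPM in NS and 44.7 in ND, and Igf2 averaged 2.74 in NS and 49.4, 120 and 82.7 at the rising doses.

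Sorbitol at 200 mM with LIF raised Igf2, Peg10, Krt18 and Zfp36l3 and lowered Ccnd1 and Cfc1. Igf2, an imprinted fetal growth factor, stood at 49.4 ± 12 CPM against 2.74 ± 0.86 in NS (SD, n = 3 per group), a log2 change of 4.20 ± 0.38 (SE) with an adjusted p of 4.32e-05 in edgeR's quasi-likelihood test. Peg10, an imprinted retrotransposon-derived gene needed for placental development, rose from 20.3 ± 3.04 to 157 ± 58.9 CPM (log2 change 2.94 ± 0.38, adjusted p = 0.00196). Krt18, a keratin of simple epithelia that includes the trophectoderm, rose by 3.13 ± 0.54 (adjusted p = 0.0122). Zfp36l3, a placental member of the tristetraprolin family, rose by 3.51 ± 0.57 (adjusted p = 0.00854). Ccnd1, which encodes the G1 cyclin D1, fell from 114 ± 31.6 to 25.3 ± 7.45 CPM (log2 change -2.16 ± 0.35, adjusted p = 0.00899). Cfc1, a Nodal co-receptor gene, fell by 3.10 ± 0.62 (adjusted p = 0.0338). Slc5a3, the sodium and myo-inositol transporter induced by hypertonic medium, was 1.60 ± 0.36 higher on the log2 scale, with an adjusted p of 0.0504.

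In the lists, 3 of the 15 trophoblast genes rose at 200 mM, Krt18, Gata2 (log2 change 3.32) and Plac1, and 5 did when adjusted over the list alone (camera adjusted p = 8.24e-06, and adjusted p = 0.102 with an estimated correlation). Of 15 imprinted genes, Igf2 and Peg10 rose, with 3 up and 1 down adjusted over the list alone (adjusted p = 0.00591, and adjusted p = 0.114 with an estimated correlation). Of 15 osmoadaptive genes 1 rose, Akr1b8, an aldo-keto reductase gene (log2 change 2.43), and 2 did adjusted over the list alone (0.00386, and adjusted p = 0.151 with an estimated correlation). Of 13 endoderm genes the basement membrane collagen gene Col4a2 rose (2.54) and the lipid carrier gene Apoe fell (-0.99), with 3 up and 1 down adjusted over the list alone, and the list's test was up (0.00512, and adjusted p = 0.151 with an estimated correlation). The primitive streak list of 6 genes moved up with 0 past in edgeR and 1 adjusted over the list alone (0.0418, and adjusted p = 0.151 with an estimated correlation). The cell cycle list of 27 genes moved down with 1 past, Ccnd1 (0.00395, and adjusted p = 0.151 with an estimated correlation). So did the cholesterol synthesis list of 22 with 0 past in edgeR (0.0418, and adjusted p = 0.587 with an estimated correlation). The ribosomal list moved up (0.000208, and adjusted p = 0.618 with an estimated correlation) with 1 of 77 past, Rpl10l, a retrocopy whose reads may be shared with Rpl10. Its median change was 0.64 between the libraries of replicate 1, 0.56 between those of replicate 2 and -0.15 between those of replicate 3.

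In all, 38 genes rose and 17 fell at 200 mM, and 1031 had an unadjusted p under 0.05. In a fit of the NS and 200 mM libraries alone 1 gene rose and 0 fell in edgeR. With the replicate number as a block, which pairs these groups by the check given among the methods, 150 rose and 118 fell, and 7 of the 8 list calls stood, that of the primitive streak list being lost (adjusted p = 0.0534). With replicates 2 and 3 alone 4 genes rose and 0 fell, and replicate 1 allows no test. The count was 12 without NS 1, 13 without NS 2, 150 without NS 3, 33 without Sorb200 1 and 22 without Sorb200 3. Igf2 and Peg10 stood without any 1 library. Zfp36l3 was lost without NS 1 (adjusted p = 0.0639) or NS 2 (0.0584), Krt18 without NS 1 (0.0628) or NS 2 (0.108). Rpl10l was lost without NS 1 (0.0839) and Ccnd1 without NS 1 (0.0555) or Sorb200 3 (0.053). Cfc1 was lost without any 1 library except NS 3 and Sorb200 2 (between 0.108 and 0.151). Akr1b8 was lost without NS 1, Sorb200 1 or Sorb200 3 (between 0.0952 and 0.18), and Apoe without any 1 library except NS 3 (between 0.11 and 0.225). The trophoblast and osmoadaptive lists stood without any 1 library. The endoderm call was lost without NS 1 (0.0547) or Sorb200 1 (0.0646), and the imprinted call without Sorb200 1 (0.0571). The ribosomal call was lost without NS 1 (0.0547) and the cell cycle call without NS 3 (0.102) or Sorb200 1 (0.0646). The streak call was lost without NS 1 (0.138), NS 2 (0.0629), Sorb200 1 (0.0646) or Sorb200 3 (0.199). The cholesterol call was lost without NS 1 (0.0831), NS 2 (0.25), Sorb200 1 (0.174) or Sorb200 3 (0.0731).

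At 250 mM sorbitol Igf2, Plac1, Gata2, Krt8, Hspb1 and Gata6 rose, and Cfc1 and Gpx2 fell. Igf2 reached 120 ± 34.0 CPM (SD, n = 3; log2 change 5.48 ± 0.38 SE, adjusted p = 6.5e-07 in edgeR's quasi-likelihood test). Plac1, a trophoblast gene, had 149 counts against 1 in NS, a ratio of 145 whose 95% interval from counting error ran from 25.6 to 5767. Gata2, a transcription factor of trophoblast and blood progenitors, rose by 4.54 ± 0.61 (adjusted p = 0.00074). Krt8, the partner keratin of Krt18, rose from 9.61 ± 10.3 to 119 ± 16.2 CPM (log2 change 3.72 ± 0.61, adjusted p = 0.00367). Hspb1, a small heat shock protein gene, rose from 163 ± 41.3 to 661 ± 65.3 CPM (2.02 ± 0.25, adjusted p = 0.000377). Gata6, a transcription factor of primitive endoderm, rose from 3.31 ± 2.22 to 24.3 ± 8.12 CPM (3.0 ± 0.60, adjusted p = 0.0124). Cfc1 fell by 3.99 ± 0.67 (adjusted p = 0.00416). Gpx2, a glutathione peroxidase gene whose reads may be shared with the pseudogene Gpx2-ps1, fell by 3.23 ± 0.47 (adjusted p = 0.00144).

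Of the 15 trophoblast genes, 7 rose at 250 mM and 7 did adjusted over the list alone (camera adjusted p = 2.14e-10, and 0.0146 with an estimated correlation). Among 13 endoderm genes 4 rose and Apoe fell, with 5 up and 1 down adjusted over the list alone (0.0031, and adjusted p = 0.13 with an estimated correlation). Among 15 imprinted genes 4 rose and Meg3, a maternally expressed long RNA, fell, with 4 up and 2 down adjusted over the list alone (0.0031, and adjusted p = 0.0798 with an estimated correlation). Those that rose included Igf2, Peg10 (log2 change 3.34) and the cell cycle inhibitor gene Cdkn1c (2.53). Of 15 osmoadaptive genes 2 rose, Akr1b8 (2.73) and the inducible Hsp70 gene Hspa1b (2.3), which the heat shock list also holds, and 3 did adjusted over the list alone (0.00212, and adjusted p = 0.13 with an estimated correlation). The cholesterol synthesis list moved down (0.000275, and adjusted p = 0.231 with an estimated correlation), with 1 of 22 members past and 12 adjusted over the list alone. The ribosomal list moved up at 0.0376 (adjusted p = 0.929 with an estimated correlation), with 2 of 77 past, Rpl10l (1.31) and Rps6 (1.17), both with near-identical copies. That call was lost without NS 1 (0.273), NS 2 (0.132) or Sorb250 3 (0.0866), and NS 1 and NS 2 are the libraries with low ribosomal expression.

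In all, 189 genes rose and 231 fell at 250 mM, and 137 and 155 in a fit of the NS and 250 mM libraries alone. Scaled by library totals alone the count was 372, of which 205 rose and 167 fell, so the majority turned. With replicates 2 and 3 alone 22 rose and 6 fell, and replicate 1 allows no test. The count was 84 without NS 1, 87 without NS 2, 1413 without NS 3, and 109, 94 and 132 without Sorb250 1, 2 and 3. The majority turned without NS 3 (742 rose and 671 fell) and without Sorb250 1 (61 and 48), 2 (51 and 43) or 3 (80 and 52). Igf2, Plac1, Gata2, Krt8, Peg10, Akr1b8, Hspb1, Gpx2 and Cfc1 stood without any 1 library. Gata6 was lost without NS 1, NS 2, Sorb250 1 or Sorb250 2 (adjusted p between 0.0506 and 0.0746) and Cdkn1c without NS 1 (0.0565). Apoe was lost without any 1 library except NS 3 (between 0.0539 and 0.0874). Rpl10l was lost without NS 1 or any 1 of the Sorb250 libraries (between 0.0582 and 0.103), and Rps6 without any 1 library except NS 3 (between 0.0874 and 0.169).

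**Figure D2:**
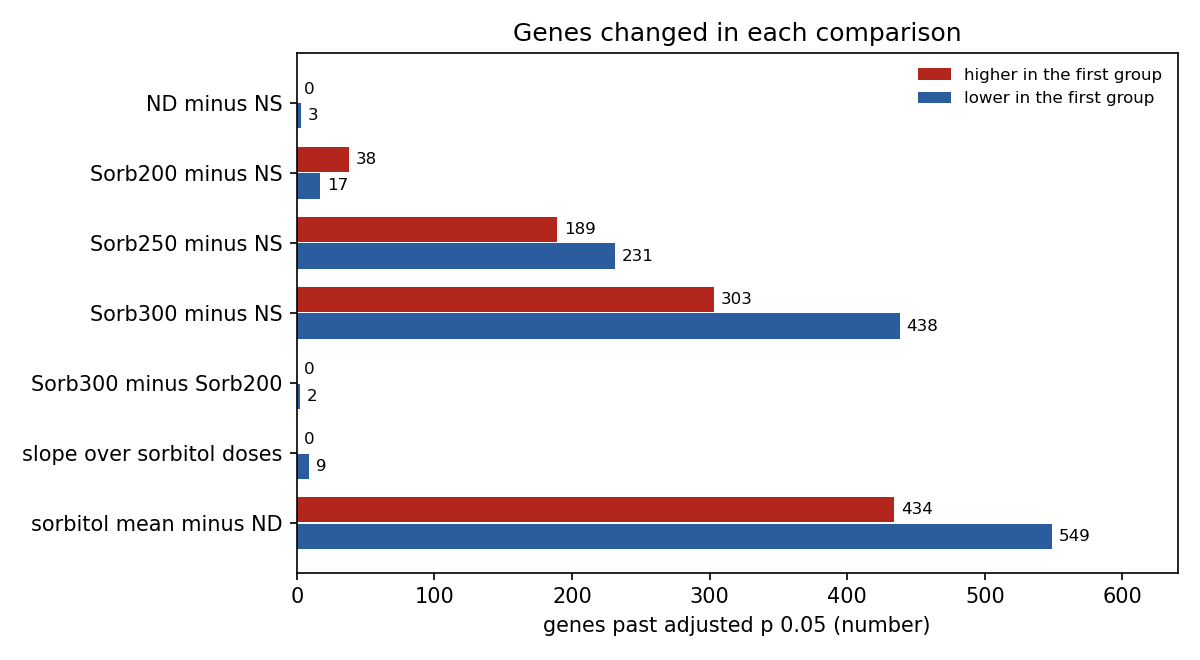
Number of genes past an adjusted p of 0.05 in each of the 7 comparisons (horizontal axis), with red bars for genes higher and blue bars for genes lower in the first-named group, or rising and falling with dose for the slope. The bars show 3 lower genes for ND minus NS, 303 higher and 438 lower for sorbitol at 300 mM minus NS, 2 lower for 300 minus 200 mM, and 434 higher and 549 lower for the sorbitol mean minus ND.

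At 300 mM sorbitol 6 of 15 trophoblast genes and 4 of 13 endoderm genes rose (each camera adjusted p = 0.0427 with an estimated correlation). Of 22 cholesterol synthesis genes 12 fell and of 21 glycolysis genes 6 (camera adjusted p = 0.0723 and 0.257 with an estimated correlation, past the threshold only with the preset one). Igf2 stood at 82.7 ± 11.6 CPM (SD, n = 3; log2 change 4.95 ± 0.38 SE, adjusted p = 3.2e-06 in edgeR's quasi-likelihood test). Col4a2 rose from 2.60 ± 0.18 to 26.7 ± 7.19 CPM (3.34 ± 0.54, adjusted p = 0.00256). Hspb1 rose to 714 ± 58.8 CPM (2.13 ± 0.25, adjusted p = 0.000191). Egln3, an oxygen-sensing prolyl hydroxylase gene, fell from 72.9 ± 22.1 to 3.49 ± 1.93 CPM (-4.38 ± 0.48, adjusted p = 0.000191). Aldoc, a glycolytic aldolase gene, fell from 170 ± 12.1 to 23.8 ± 12.4 CPM (-2.80 ± 0.52, adjusted p = 0.00516). Insig1, a sterol-responsive regulator of SREBP, fell from 130 ± 70.9 to 19 ± 6.58 CPM (-2.76 ± 0.55, adjusted p = 0.00809). Nanog (0.02 ± 0.58), Zfp42 (0.75 ± 0.60), Pou5f1 (-0.49) and Sox2 (-0.68 ± 0.30, adjusted p = 0.176), Slc5a3 (0.89, adjusted p = 0.148) and the endoderm adaptor gene Dab2 (0.56) did not pass. Cdx2, a trophectoderm regulator, had 8 counts against 0 in NS. Sox17 had 19 against 5 and Akr1b3, the aldose reductase gene that makes sorbitol in hypertonic medium, had 19 against 6, too few to be tested.

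Of 15 trophoblast genes 6 rose at 300 mM and 8 did adjusted over the list alone (camera adjusted p = 1.27e-06, and 0.0427 with an estimated correlation), among them Gata2 (log2 change 4.41), Krt8 (3.30) and Krt18 (2.93). Of 13 endoderm genes 4 rose, including Col4a1 (2.27) and Gata6 (2.63), and Apoe fell, with 5 up and 1 down adjusted over the list alone (1.06e-05, and 0.0427 with an estimated correlation). Of 6 primitive streak genes Eomes (1.73), which trophoblast cells also express, and Bmp4 (2.19) rose, with 4 adjusted over the list alone (0.0111, and adjusted p = 0.0723 with an estimated correlation). Of 15 osmoadaptive genes 2 rose, Akr1b8 (2.77) and Slc5a5 (1.79), which encodes the sodium iodide symporter and no osmolyte transporter, and 4 did adjusted over the list alone (0.000377, and adjusted p = 0.0723 with an estimated correlation). Of 15 imprinted genes 3 rose and Meg3 fell (-1.91), with 4 up and 2 down adjusted over the list alone (0.00956, and adjusted p = 0.0723 with an estimated correlation). Of 15 heat shock genes 1 rose, Hspb1, as it did adjusted over the list alone (0.0467, and adjusted p = 0.257 with an estimated correlation). The ribosomal list moved up with 2 of 77 past, Rpl10l (1.61) and Rps6 (1.28) (0.00484, and adjusted p = 0.674 with an estimated correlation), and the call was lost without NS 1 (0.0558), a library of low ribosomal expression.

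Of 22 cholesterol synthesis genes 12 fell at 300 mM and 14 did adjusted over the list alone (camera adjusted p = 7.38e-09, and adjusted p = 0.0723 with an estimated correlation). Lss, the gene of lanosterol synthase, fell by 2.05 ± 0.40 and Dhcr7, whose enzyme makes cholesterol from 7-dehydrocholesterol, by 1.88, while Insig1 is a regulator and not an enzyme of the pathway. Of 21 glycolysis genes 6 fell and 7 did adjusted over the list alone (0.000255, and adjusted p = 0.257 with an estimated correlation). These were Aldoc, Aldoa (-1.42), Ldha, Ldhb (-1.58), Gpi1 and Bnip3 (-2.23), the last of which encodes a mitophagy receptor and no glycolytic enzyme. Of 9 histone genes 4 fell and Hist1h2bc rose (3.14), with 6 down and 1 up adjusted over the list alone (0.0149, and adjusted p = 0.334 with an estimated correlation), and near-identical copies make single histone genes uncertain.

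In all, 303 genes rose and 438 fell at 300 mM, and 189 and 273 in a fit of the NS and 300 mM libraries alone. With replicates 2 and 3 alone 51 rose and 65 fell, and replicate 1 allows no test. The count was 291 without NS 1, 250 without NS 2, 1500 without NS 3, and 408, 210 and 266 without Sorb300 1, 2 and 3. Igf2, Gata2, Krt8, Krt18, Col4a1, Col4a2, Hspb1, Hist1h2bc, Egln3, Aldoc, Bnip3, Lss and Dhcr7 stood without any 1 library. Gata6 was lost without NS 1, NS 2, Sorb300 2 or Sorb300 3 (adjusted p between 0.0514 and 0.0885) and Bmp4 without NS 2, Sorb300 2 or Sorb300 3 (between 0.0556 and 0.0765). Eomes was lost without any 1 library except NS 3 (between 0.0686 and 0.149) and Apoe likewise (between 0.0674 and 0.128). Meg3 was lost without any 1 library except NS 3 (between 0.0548 and 0.125), and Rps6 without NS 1, NS 2 or Sorb300 3 (between 0.0755 and 0.0832). Insig1 was lost without Sorb300 2 (0.0528), Ldhb without Sorb300 3 (0.0526), and Aldoa without NS 1, Sorb300 2 or Sorb300 3 (between 0.0794 and 0.0892). The heat shock call was lost without NS 2 (0.0712), NS 3 (0.0573), Sorb300 1 (0.0685) or Sorb300 3 (0.054), and the histone call without Sorb300 1 (0.0514).

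**Figure D3:**
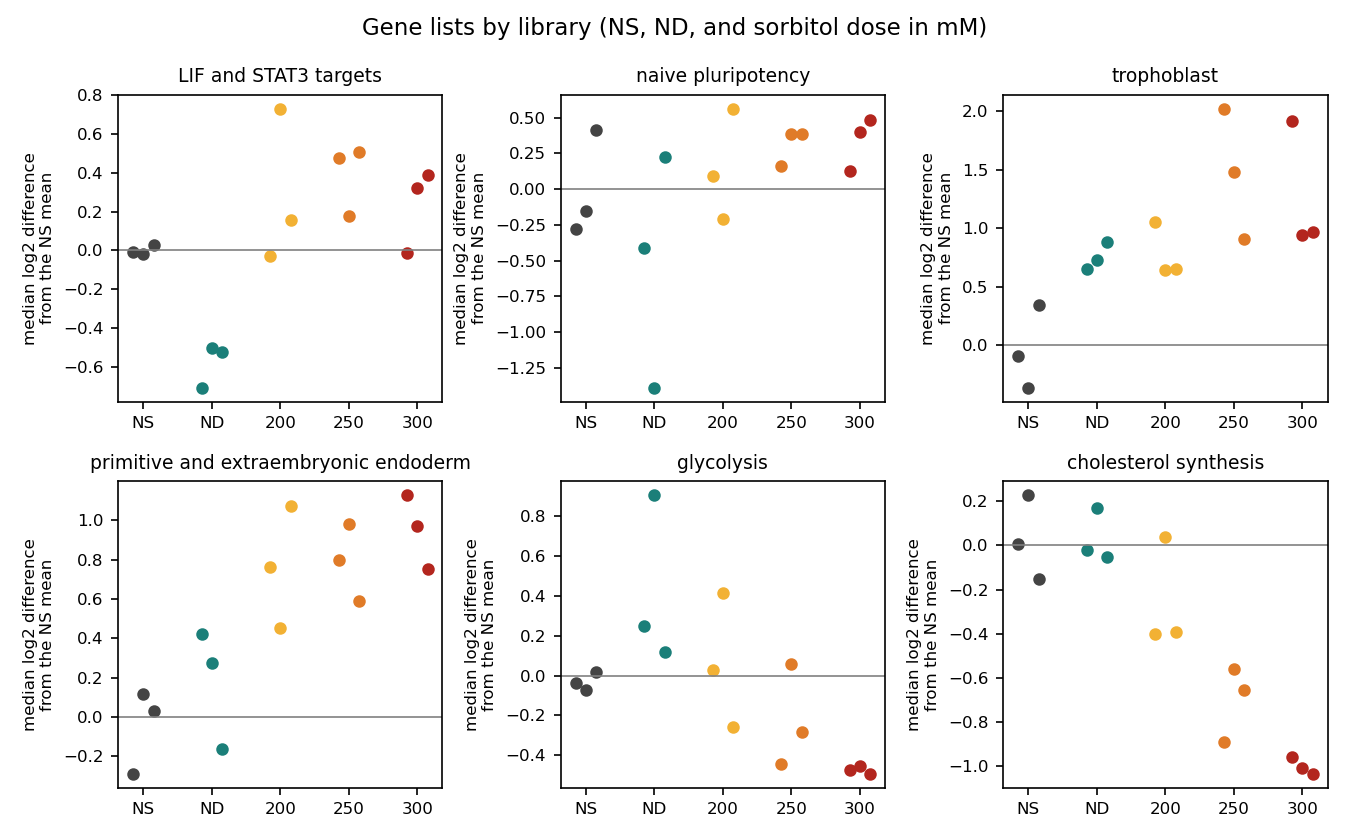
Median over the genes of a list of each library's log2 CPM minus the NS mean (vertical axis, log2), for 6 gene lists, with 1 point for each of the 15 libraries in the groups NS, ND and sorbitol at 200, 250 and 300 mM, and a grey line at 0. The cholesterol synthesis list lies between -0.15 and 0.23 in the NS libraries and between -1.03 and -0.96 in the libraries at 300 mM.

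Comparing the doses with each other asked which genes followed the amount of sorbitol. Egln3 fell by 3.48 ± 0.49 on the log2 scale from 200 to 300 mM (3.49 ± 1.93 against 39.8 ± 15.5 CPM, SD, n = 3 per group, adjusted p = 0.018 in edgeR's quasi-likelihood test). Cox6b2, a cytochrome oxidase subunit gene outside the naming rule and chosen after its values were seen, was lower as well, at 2.54 ± 0.71 against 14.3 ± 2.27 CPM (adjusted p = 0.0287). Across the 9 sorbitol libraries 9 genes fell with dose and 0 rose in edgeR without a block. The slopes per 50 mM were -1.60 ± 0.24 for Egln3, -1.36 ± 0.23 for Aldoc and -1.16 ± 0.19 for Ndrg2. They were -0.97 ± 0.16 for Scd1, a stearoyl-CoA desaturase gene, and -0.90 ± 0.15 for Pfkfb3, a regulator of glycolytic flux (each adjusted p = 0.0441). Cox6b2 (-1.28), Prkcb (-1.45), Prelid2 (-0.76) and G530011O06Rik (-0.75), named after their values were seen, made up the rest.

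Between 300 and 200 mM the cholesterol synthesis list had a median log2 change of -0.80 (camera adjusted p = 9.08e-11, and adjusted p = 0.0899 with an estimated correlation) and the glycolysis list one of -0.71 (1.73e-09, and adjusted p = 0.109 with an estimated correlation). No member of either passed over all genes in edgeR, and 8 of 22 and 6 of 21 did adjusted over the list alone. The endoderm list moved up (0.000586, and adjusted p = 0.0899 with an estimated correlation), as did the trophoblast list (0.0417, and adjusted p = 0.412 with an estimated correlation), and the histone list moved down (0.0462, and adjusted p = 0.534 with an estimated correlation), with 0 members past in edgeR. Along the dose trend 2 of 21 glycolysis genes fell, Aldoc and Pfkfb3, and 9 did adjusted over the list alone (2.02e-11, and adjusted p = 0.0891 with an estimated correlation). Of 21 cholesterol synthesis genes 0 passed in edgeR and 12 fell adjusted over the list alone (2.02e-11, and adjusted p = 0.0891 with an estimated correlation). The endoderm list of 12 genes (0.00303, and adjusted p = 0.0891 with an estimated correlation) and the primitive streak list of 5 (0.00749, and adjusted p = 0.194 with an estimated correlation) moved up with 0 past. In both dose tests the glycolysis, cholesterol and endoderm calls stood without any 1 library. The trophoblast call was lost without Sorb200 2 (0.243), Sorb200 3 (0.055) or Sorb300 1 (0.356), and the histone call without Sorb200 2 (0.666), Sorb200 3 (0.184) or Sorb300 1 (0.156). The streak call along the trend was lost without any 1 library except Sorb200 1 (between 0.054 and 0.171).

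Between 300 and 200 mM, 873 genes had an unadjusted p under 0.05 and DESeq2 called 35, against 2 in edgeR. Along the trend DESeq2 called 75 against 9, and 14 of the 75 rose while 61 fell. With the replicate block 18 genes rose and 93 fell along the trend in edgeR. Scaled by library totals alone, edgeR called 0 genes along the trend, where 1025 had an unadjusted p under 0.05 in the test with TMM factors. With replicates 2 and 3 alone 0 genes passed between 300 and 200 mM and 27 fell along the trend, of which 6 were among the 9. Replicate 1 allows no test between 300 and 200 mM, and its 3 libraries were not tested alone along the trend. In a fit of the 200 and 300 mM libraries alone, without the groups that otherwise add to the estimate of spread, edgeR called 0 genes between them. Leaving out Sorb200 3 gave 10 genes between 300 and 200 mM, leaving out Sorb200 1 gave 1, and leaving out Sorb200 2 or any 1 of the Sorb300 libraries gave 0. Along the trend 21 genes passed without Sorb200 1, 41 without Sorb200 3 and 0 without any other 1 library, where the adjusted p of Egln3 was between 0.0565 and 0.275.

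Sorbitol-treated cells kept LIF, so the mean of the 3 doses was set against ND to compare hyperosmotic medium with LIF directly against LIF withdrawal (n = 9 against 3). The sides differ both in sorbitol and in LIF, so this comparison alone cannot assign a difference to either. The comparison of ND with NS differs in LIF alone, and that of each dose with NS in sorbitol alone. Tbx3, a naive pluripotency regulator, stood at 399 ± 50.3 CPM in sorbitol and 37.5 ± 29.2 in ND (SD), a log2 difference of 3.38 ± 0.37 (SE) with an adjusted p of 3.4e-05 in edgeR's quasi-likelihood test. Klf4 (407 ± 176 against 44.7 ± 15.8 CPM, log2 difference 3.12 ± 0.38) and Stat3 itself (152 ± 22.3 against 57.4 ± 21.4 CPM, 1.41 ± 0.24) were higher with sorbitol. So were Igf2 (3.74 ± 0.32, adjusted p = 6.5e-06) and Hand1, a regulator of trophoblast giant cells and mesoderm (3.10). Dppa3, a germline and naive pluripotency gene (-1.93 ± 0.35, adjusted p = 0.00186), Ldhb (-1.97 ± 0.25, adjusted p = 0.000125) and Cfc1 (-4.53) were lower. Zfp42 (0.98, adjusted p = 0.263), Nanog (0.19), Pou5f1 (-0.13) and Sox2 (0.06) did not pass.

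Of 11 LIF and STAT3 targets 4 were higher than in ND, and 5 adjusted over the list alone (camera adjusted p = 0.00019, and 0.0311 with an estimated correlation). Of 18 naive genes 5 were higher, among them Klf4, Tbx3 and Klf5 (1.31), and Dppa3 was lower, with 8 and 2 adjusted over the list alone (0.000201, and adjusted p = 0.195 with an estimated correlation). Of 12 general pluripotency genes 4 were higher, with 4 higher and 1 lower adjusted over the list alone (0.00929, and adjusted p = 0.304 with an estimated correlation). Of 13 endoderm genes 6 were higher, led by the laminin gene Lama1 (2.88), and 1 was lower (0.00924, and adjusted p = 0.148 with an estimated correlation). Of 15 trophoblast genes 5 were higher and 2 lower, the latter being the X-linked homeobox genes Rhox6 and Rhox9 (0.011, and adjusted p = 0.174 with an estimated correlation). Higher with adjusted p = 0.148 with an estimated correlation were also the osmoadaptive list (0.00115; 4 of 15 past), the imprinted list (0.0319; 3 of 15 higher and 1 lower), the Hox list (0.0145; 1 of 3, Hoxc13) and the primitive streak list (0.0458; 1 of 6, Bmp4). Lower, again with adjusted p = 0.148 with an estimated correlation, were the glycolysis list (7.78e-06; 8 of 21 past), the cholesterol list (0.000101; 9 of 22) and the cell cycle list (0.00929; Ccnd1, Cdkn2a and Top2a of 27). Adjusted over the list alone, 10 glycolysis and 10 cholesterol genes were lower. The ribosomal list was lower (0.0132, and adjusted p = 0.571 with an estimated correlation), with Rpl10l and Rpl39l higher and Rpl22 and Rps26 lower of 77, and ND 2 had the highest ribosomal expression of the 15 libraries.

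In all, 434 genes were higher and 549 lower with sorbitol than in ND. Scaled by library totals alone 494 were higher and 418 lower, so the majority turned. In the test with TMM factors 2324 genes had an unadjusted p under 0.05. With replicates 2 and 3 alone 193 were higher and 211 lower, and 379 of those 404 were among the 983, while replicate 1 has 1 ND library and allows no test here. The count was 646 without ND 1 and 537 without ND 2. Tbx3, Klf4, Stat3, Igf2, Hand1, Lama1, Dppa3, Ldhb, Ccnd1 and Cfc1 stood without any 1 library, and Cdkn2a was lost without ND 2 (adjusted p = 0.0645) and Bmp4 without ND 1 (0.0508) or ND 2 (0.0575). Rpl22 and Rps26 were lost without ND 2 (0.313 and 0.181), Sorb250 1 or Sorb250 2 (between 0.0501 and 0.0549), and Rps26 also without Sorb300 2 (0.0585). Among the lists, the general pluripotency call was lost without ND 2 (0.115) and the ribosomal call without ND 2 (0.845). The imprinted call was lost without ND 2 (0.208), Sorb200 1 (0.0921), Sorb250 1 (0.0634) or Sorb300 3 (0.0549). The trophoblast call was lost without ND 1 (0.0518), and the streak call without ND 1 (0.113), ND 2 (0.0646), Sorb200 3 (0.0604) or Sorb300 3 (0.0514).

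In the edgeR fit without a block, no gene was called both after LIF withdrawal and at any sorbitol dose. The withdrawal test called only 3 genes, and lists of these sizes that were independent would share 0.01, 0.07 and 0.14 lowered genes with the tests of 200, 250 and 300 mM. DESeq2's calls shared 4, 5 and 5 genes of one direction and 2, 5 and 5 of opposite direction. The covariance of the log2 changes of withdrawal and of each dose over the tested genes was 0.0773, 0.1007 and 0.077. Unchanged groups, simulated with NS libraries drawn anew from the NS means, gave 0.0989, 0.099 and 0.0983. Between the doses, Igf2 and Peg10 were among 36 genes that rose at both 200 and 250 mM, and 17 fell at both, against 0.76 and 0.42 for independent lists. At 200 and 300 mM 34 rose and 17 fell in both tests, against 1.23 and 0.79, and at 250 and 300 mM 151 rose and 185 fell, against 6.10 and 10.8. No gene was called in opposite directions at these doses in edgeR. The covariances of the doses were 0.321, 0.332 and 0.530, which exceeded the simulated values by 0.222, 0.233 and 0.431. The simulated libraries were drawn independently. Their values hold each gene's spread as estimated over all 15 libraries. They lack any spread of the real NS libraries beyond that, differences shared by many genes of a library, and the correlations by replicate number. In the 20 simulated sets, at most 0 genes were called in 1 direction at both doses of any pair, but these sets held no changed genes. Since the 3 NS libraries cannot be divided into parts of at least a pair each, part of the excess of shared calls may come from the shared controls.

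The authors' deposited tables held their own comparison of each condition with NS. At an FDR under 0.05 the authors' deposited tables listed 16 genes for ND (5 higher, 11 lower), 140 at 200 mM (89 and 51), 595 at 250 mM (290 and 305) and 935 at 300 mM (420 and 515). Of these genes, 16, 122, 508 and 784 were tested here, each with the sign that the authors' deposited tables give it, and 3, 55, 400 and 683 also passed in the quasi-likelihood test.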

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

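The tests of the shared spread, of the depth, of fibroblast RNA and of splits within replicate numbers in this part were chosen after the results they bear on were seen. The correction for GC content and length was also chosen after the data were seen. Tests of a difference between treatments singled out 5 genes. Klf4, Bcl3 and Tdgf1, which fell after LIF withdrawal, differed between the sorbitol mean and ND by 3.12, 3.13 and 1.79 on the log2 scale. They were picked for being low in the ND libraries, which this comparison used again. A difference in this direction was thus largely set by the choice. Egln3 and Cox6b2 differed between 300 and 200 mM sorbitol by -3.48 and -2.39. No rule for single outlying samples was applied, as groups of 3 libraries are too small for one. NS was visibly split all the same. Its chi-square per degree of freedom was 5.16 between NS 1 and NS 2, and 29.3 and 13.35 between these and NS 3. Sorb200 1 and Sorb200 3 also differed widely (20.04). Which side of NS departs cannot be told from 3 libraries.

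LIF withdrawal changed 3 genes in 72 h, where sorbitol at 300 mM changed 741. Lower depth of the ND libraries as a group is argued against by the mean total counts, which were 1.07 times those of the 300 mM libraries. In replicates 1, 2 and 3, ND had 2197986, 968556 and 1229075 counts, and 300 mM had 1909528, 1160231 and 1036314. ND 2 thus had fewer, and it had the lowest total and the fewest detected genes (12407) of the 15 libraries. An exchange of ND and NS libraries is argued against by the LIF and STAT3 targets without Klf4. Their lowest NS median and highest ND median lay 0.365 apart on the log2 scale. A spread shared by libraries of 1 replicate number remains open, since 40 genes passed with the number as a block. A response to LIF withdrawal that is small at 72 h stays open as well and was not tested apart from this. The spread within NS also stays open, since 74 genes passed without NS 3 and 0 without NS 1 or NS 2. Of the 10 splits of the 6 libraries, 2 gave at least 3 genes, too few splits for a share under 0.05, and NS 1, NS 2 and ND 1 against the rest gave 722, which points to a structure of the samples.

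Trophoblast genes were higher with sorbitol at 300 mM. A single NS library as the source is argued against by the list's adjusted p, at most 6.61e-06 without any 1 of them, and GC content or length by an adjusted p of 3.69e-06 with the correction. RNA of fibroblasts is argued against by their abundant collagen transcripts Col1a1, Col1a2 and Col3a1, which summed to 2.01 ± 2.19 CPM at 300 mM and 2.89 ± 1.39 in NS while Krt18 was 129 CPM higher, although Acta2, a smooth muscle actin gene chosen after its values were seen, rose to 15 ± 13.1 CPM and the test run first, on list medians, decided nothing (0.48 against 1.16 for trophoblast, with 3 of 5 measured fibroblast genes higher). A response of the stem cells to hyperosmotic medium is a hypothesis left by these tests, which were run on the data that showed it, but not the only one, since the list also moved up against NS in ND, without sorbitol (median log2 change 0.91, adjusted p = 0.000324, and adjusted p = 0.13 with an estimated correlation). The 10 splits were too few for a share under 0.05: 1 gave as many genes as the 741 at 300 mM, and the highest other, NS 1, NS 2 and Sorb300 1 against the rest, gave 455.

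The glycolysis and cholesterol synthesis lists were lower at 300 than at 200 mM with the preset correlation, but not past the threshold with an estimated one (adjusted p = 0.109 and 0.0899), and 0 of their members passed singly in edgeR, where 873 genes had an unadjusted p under 0.05 and DESeq2 called 35. A difference between experiments of 1 replicate number is argued against by the 3 differences between libraries of 1 number, whose highest list medians were -0.52 for glycolysis and -0.56 for cholesterol synthesis. GC content or length is argued against by corrected medians of -0.77 and -0.79. The glycolysis median was -0.66 with library totals against -0.71 with TMM, and the median of all tested genes was 0.03 against -0.017. Such a change of scale moves all genes nearly alike, so it cannot decide on composition of the libraries. It shows only that the choice between TMM and library totals did not make the fall. A response to the dose of sorbitol is a hypothesis left open by these tests, which were run on the data that showed it. The 10 splits of these 6 libraries were too few for a share under 0.05: 1 gave at least 2 genes, and the highest other gave 0.

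The other counts were set against splits of their libraries as well. At 200 mM 2 of 10 splits gave at least 55 genes, and NS 1, NS 2 and Sorb200 1 against the rest gave 1366, which points to a structure of the samples; at 250 mM 1 of 10 gave at least 420, and the highest other gave 0. Both have too few splits for a share under 0.05. For the dose trend 4 of 100 drawn splits gave at least 9 genes, the real one included, which is under 0.05 by 1 split and does not exclude chance firmly. The highest other gave 737, which points to a structure of the samples. Splits that put together the libraries of 1 replicate number varied: those of replicate 3 gave 431 and 0, those of replicate 1 gave 290 once and 0 or 1 otherwise, and those of replicate 2 gave 0. The value with the replicate block was 111. Of 100 splits that kept 1 library of each number at each dose, 1 gave at least 9 genes, the real one, and the highest other gave 0. With the block 2 gave at least 111, the real one included, and the highest other gave 171. Both shares are under 0.05 among these splits. They were chosen after the results were seen, so they do not exclude chance firmly. For the sorbitol mean minus ND 1 of 100 splits, drawn without regard to replicate number, gave at least 983 genes and the highest other gave 5. That share is under 0.05, but splits within replicate numbers were not run for this comparison.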

How the results depend on the processing

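The settings with replicates 2 and 3 alone, the likelihood ratio test and the GC and length correction were chosen after the data were seen. No named gene that was called turned its direction under any setting run, and no called list passed in the other direction. Without ND 2, 2 called lists turned without passing: the oxidative phosphorylation list in ND minus NS (adjusted p = 0.949) and the ribosomal list in the sorbitol mean minus ND (0.845). Lists that were not called could turn as well, as the chromatin regulator list at 250 mM did with the replicate block, and so could genes that were not called. The balance of higher and lower genes turned in some fits. For ND minus NS it went from 0 and 3 to 46 and 28 without NS 3. At 300 mM minus NS it became even without Sorb300 2 (105 and 105, against 303 and 438) and did not turn. At 250 mM minus NS 189 rose and 231 fell, against 205 and 167 with library totals, 38 and 29 against a 1.5-fold change, 22 and 6 with replicates 2 and 3 alone, and more higher than lower with the replicate block (844 and 839; 876 and 847 with the correction) and without NS 3 or any 1 Sorb250 library. For the sorbitol mean minus ND it turned from 434 and 549 to 494 and 418 with library totals. Counts of genes stayed within 1.5 times in 45 fits and moved in 90, counts of lists stayed in 106 and moved in 22, and of the single lists' calls 851 were the same, 171 weaker and 2 moved. Named genes were on the same side of the threshold in 3711 fits, weaker in 528 and stronger in 10, and 62 values moved. For every count that moved, the cause was not tested, beyond the fewer libraries or other genes that a setting uses. Values follow in the order ND, 200, 250 and 300 mM minus NS, 300 minus 200 mM, the trend, and the sorbitol mean minus ND, where the counts were 3, 55, 420, 741, 2, 9 and 983. RLE factors gave 1 for ND, and library totals 0 for the trend. Without a filter 37, 161 and 825 genes passed for ND, 200 and 250 mM, 58 for 300 minus 200 mM and 148 for the trend, and DESeq2 gave 33, 161, 742, 35 and 75 for these. With the replicate block 40, 268, 1683, 1869, 119, 111 and 1830 passed, and with the block and the GC and length correction 55, 305, 1723, 1927, 129, 92 and 1819. The correction alone gave 5 for 300 minus 200 mM. With the compared groups alone 0, 1, 462 and 0 passed for ND, 200 mM, 300 mM and 300 minus 200 mM, and 2 for the trend with all 15 libraries. Against a 1.5-fold change the counts were 0, 12, 67, 192, 1, 0 and 299, and with replicates 2 and 3 alone 0, 4, 28, 116, 0, 27 and 404. The likelihood ratio test without a filter gave 16, 158, 664, 35 and 145 for ND, 200 and 250 mM, 300 minus 200 mM and the trend. Leaving out 1 library gave 0 to 74, 12 to 150, 84 to 1413, 210 to 1500, 0 to 10, 0 to 41 and 537 to 1120 genes. Of 9, 8, 6, 10, 5, 4 and 13 lists, an estimated correlation left 1, 0, 1, 2, 0, 0 and 1, and fry left 1, 3, 5, 9, 3, 2 and 12. In all, fry called 1 list for ND, 4 for 200 mM (the fourth being the Hox genes), 9 for 250 mM, 12 for 300 mM, 3 for 300 minus 200 mM, 2 for the trend and 15 for the sorbitol mean minus ND. Without a filter 7 lists passed for the trend, and leaving out 1 library gave 5 to 10, 4 to 10, 6 to 10, 9 to 12, 3 to 8, 3 to 7 and 11 to 17 lists. Between 300 and 200 mM the replicate block left 3 lists, and 3 with the correction. All genes called without the block were called with it. Of the comparisons of 2 groups, only 200 mM minus NS passed the check of the numbers, and its pairing is uncertain for replicate 2. The trend and the sorbitol mean minus ND mix groups that passed and groups that did not. With the block 5, 7 and 8 genes were called in 1 direction and 2, 3 and 3 in opposite directions after LIF withdrawal and at 200, 250 and 300 mM, against 0 without it. At these depths most 2-fold changes fall below what the test detects, as between 7.10% and 34.3% of them were recovered in simulated data.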

Other observations

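Both tests of hypotheses in this part were chosen after the dose trend had been seen. Some genes of the germline list rose and others fell with sorbitol. Taf7l, a testis paralogue of a general transcription factor subunit, rose by 2.20 on the log2 scale at 250 mM and 2.57 at 300 mM (adjusted p = 0.0239 and 0.00735 in edgeR's quasi-likelihood test, n = 3 per group), and Stra8, the retinoic acid-induced gene of meiotic entry, rose from 94.4 ± 4.92 to 256 ± 74.2 CPM at 250 mM (log2 change 1.44, adjusted p = 0.0218). Stra8 was 0.06 from NS at 300 mM, and its difference between 300 and 200 mM, -1.73, did not pass. Sycp3, a synaptonemal complex gene, fell by 2.49 at 300 mM, Prdm1, a regulator of germ cell specification, by 1.99 (adjusted p = 0.0192), and Xlr3a, which has near-identical copies, by 1.37. The germline list as a whole did not pass at 300 mM (1 of 14 members up and 3 down, camera adjusted p = 0.408). Without 1 library the calls of Stra8 and Taf7l at 250 mM were lost in 4 and 5 of 6 fits (adjusted p up to 0.104 and 0.118) and that of Prdm1 at 300 mM in 2 (up to 0.0759), while Taf7l and Xlr3a stood at 300 mM.

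Among chromatin regulators, the de novo methyltransferase gene Dnmt3b rose from 113 ± 6.52 to 357 ± 55.9 CPM at 250 mM (log2 change 1.66 ± 0.22, adjusted p = 0.000644), a call that stood without any 1 library. The Polycomb genes Ezh2 and Suz12 fell by 0.91 and 0.74 there (adjusted p = 0.032 and 0.0382), calls that were lost without any 1 library except NS 3 (adjusted p up to 0.162 and 0.145). The list of these regulators did not pass (1 of 23 up and 2 down, adjusted p = 0.991). Meg3, a maternally expressed long RNA, fell by 1.91 at 300 mM (adjusted p = 0.026, and up to 0.125 without 1 library) while the imprinted genes Igf2 and Peg10 rose. In the neuroectoderm list Stmn2 rose by 1.06 and Sox11 and Elavl3 fell by 1.26 and 1.48 at 300 mM, and the list did not pass (adjusted p = 0.0982). These calls were lost in 4 of 6 fits without 1 library for Stmn2 and in 5 for Sox11 and Elavl3. Pramel6 and Pramel7, leucine-rich repeat genes of naive and early embryonic cells, were 4.53 and 4.37 higher in the sorbitol groups than in ND.

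Since Egln3, Aldoc, Pfkfb3 and Ndrg2, which fell with dose, are known targets of hypoxia-inducible factor, a hypothesis was that genes responsive to low oxygen fall together with sorbitol dose. A list of 19 such genes without those already called had a median slope of -0.23 per 50 mM, with 18 of 19 below 0 and 0 past the threshold in edgeR (camera p = 2.67e-05, 5.33e-05 adjusted over both hypotheses, and 0.0821 adjusted with an estimated correlation, so that the call was lost). A fall would fit lower signalling through this factor at higher dose, but denser cultures at low dose, which use more oxygen, could give the same pattern, and cell density was not analysed here.

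Since Scd1, a desaturase gene under SREBP control, also fell, the other hypothesis was that fatty acid synthesis genes fall with dose as the cholesterol genes do. Of 13 such genes 10 had slopes below 0, with a median of -0.20 per 50 mM and 0 past the threshold in edgeR (camera p = 0.00165, and 0.0413 with an estimated correlation). Adjusted over both hypotheses the latter was 0.0821, so that this call was lost too. A fall would fit a lower activity of SREBP at higher dose, which may also follow from the sterol content of the cells, not analysed here.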
